A study of Homo sapiens with 8 samples.

How the data were processed

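The data are 8 arrays of 1 colour (Cy3), 4 of HSC-3 and 4 of HSC-3-M3, hybridised with labelled cRNA made from total RNA of cultured cells. Per the file headers, the scanner images were quantified with Agilent Feature Extraction 11.0.1.1, which also stands in the submitters' processing notes. The deposited values are intensities on a linear scale: the processed signal, which the software had background-subtracted within each array, and the median signals of the spot and of its local background. The deposited files also hold flags of 0 or 1 per spot (other values), set by the software per the file headers. Nothing in the headers or labels records a scaling between arrays. The deposited table of values for the series equals the mean processed signal of each probe in 100% of values, within a relative tolerance of 1e-05, so its scale is linear, it is not centred, and it has no direction of its own. Its column medians were 11.5, 10.1, 8.95 and 9.28 for HSC-3 replicates 1 to 4 and 8.75, 10.2, 9.34 and 8.16 for HSC-3-M3 replicates 1 to 4.

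Each array held 60901 spots besides 2075 control spots, which were left out. Spots flagged as non-uniform or population outliers were removed and the rest averaged to 58201 probes; 22 probes without a value on every array were dropped. No spot was saturated. Probes were named by matching their RefSeq accession, without version, to a table of the assembly GRCh38.p14. Of 33080 probes with such an accession 31104 matched, giving 22439 genes, and 27097 probes stayed unnamed here. The array design is based on build hg19, so the table served only for names and for which genes are neighbours, and no coordinate is given. All 94 probes of Y-linked genes, XIST and TSIX were left out.

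The log2 of the processed signal was taken and the array's 75th percentile over all probes subtracted. Probes were kept if well above background on at least 4 of the 8 arrays, whatever the line, which left 19992 probes. A gene took its kept probe of highest mean, giving 15106 genes. Of the called genes 44 had more than 1 kept probe, and in none did another probe pass in the opposite direction. The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05 and at least a 2-fold change. Where a gene was not well above background on any array of a line, the fold is a lower bound. It sets the bright line's mean against the dim line's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. Some probes brighter than that lowest signal are not well above background, so the bound is approximate. The bound carries no error term, and adjusted p-values belong to the fitted changes.

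Before the data were examined, 34 gene lists with 1188 symbols were fixed, together with the rule for named genes, the tests and most alternatives. Of these symbols 1160 were on the array and 993 were tested. Lists with at least 5 tested genes, and windows of 10 Mb with at least 10 tested genes, were tested with camera at a preset correlation of 0.01, two-sided, which compares a set with all other genes, and again with an estimated correlation. The function fry tested whether a list's genes move, on balance, one way or in either direction, without comparing them with other genes. List medians were also set against 10000 random lists matched on mean signal, a test chosen only after the results were seen.

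The rule for named genes has 5 parts. The first takes the 10 largest rises and 10 largest falls among called genes above background on all 8 arrays whose lines do not overlap. The second takes the 5 largest lower bounds in each direction among genes measured in 1 line only. In these parts symbols of uncharacterised loci and open reading frames were passed over. The third takes up to 4 called members of each list, the fourth a panel of 16 epithelial, mesenchymal and invasion genes whatever their values, and the fifth up to 3 called genes in each of the 3 windows of lowest p. One gene of the first part and 2 of the fourth are not reported here.

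All 8 arrays lay on 1 slide and in 1 scan. The HSC-3 arrays occupied one row of the slide and the HSC-3-M3 arrays the other, so position and line cannot be told apart. Correlation between arrays over tested genes was 0.989 to 0.997 within a line and 0.979 to 0.992 between lines. No pair of arrays was close enough to be the same sample deposited again: the SD of the difference between replicates ran from 0.24 to 0.47, the highest between HSC-3 replicates 1 and 3.

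The steps were tested on simulated data for HSC-3-M3 against HSC-3, with the means and variances of the 15106 genes and independent errors. Of 50 genes changed 1.5-fold, 54% passed the adjusted p and none the fold threshold. Of 50 genes changed 2-fold, 82% passed the adjusted p and 34% were called, and of 50 each at 3-fold and 4-fold, 100% and 98% were called. Without any change, the mean number of lists called was 0.05 and of windows 0 over 20 simulations. A list shifted by 0.3 was found in 20 of 20. Simulated genes had no correlation, so this says nothing of correlated sets. Figures were drawn with matplotlib.

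The alternatives were a normexp background correction with offset 50, median, quantile and no scaling, no filter and a filter on all 8 arrays, the mean of a gene's probes, an intensity trend with robust variance, array weights, the replicate number as a block, the deposited table of values, each array left out in turn, a 1.5-fold threshold, limma's treat against 2-fold, other list tests, and windows of 5 and 20 Mb. The normexp correction used the median spot signal, since the files used here have no column of mean signals. Chosen after seeing the data were that substitution, a percentile over probes detected on all arrays, the inclusion of unnamed probes, the removal of trends with signal level, gene density and gene length, and leaving out 2 HSC-3 arrays together. A block for the slide was not fitted, there being 1.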

Results

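HSC-3 is an established human tongue carcinoma cell line, and HSC-3-M3 is a subline of it described in the series title as highly metastatic. Total RNA from 4 samples of each line was measured on 8 one-colour expression arrays, 1 array per sample. The only comparison the labels give is the subline against its parent, and it asks which transcripts differ between a line and the highly metastatic cells derived from it. The labels do not say whether the 4 samples of a line came from separate cultures, so every p-value measures the spread between these samples, which may be technical. Between 49.0% and 50.7% of the probes on an HSC-3 array, and between 47.0% and 48.5% on an HSC-3-M3 array, were well above background. The 75th percentile of the processed signal ran from 122 to 173 on the HSC-3 arrays and from 136 to 167 on the HSC-3-M3 arrays. Levels below are log2 signals relative to that percentile on the same array, and a change is the HSC-3-M3 mean minus the HSC-3 mean. The number of arrays limits the precision.

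The largest rise among genes measured on all 8 arrays was that of LGALS7, which encodes galectin-7, a galactoside-binding lectin of stratified epithelia. Its level was 0.06 ± 0.35 (SD, n = 4) in HSC-3 and 5.56 ± 0.12 (SD, n = 4) in HSC-3-M3, a 45.4-fold difference (limma, adjusted p = 3.6e-08). A near-identical gene, LGALS7B, exists, and a probe for one may also bind transcripts of the other. The matrix metalloproteinase MMP3 (stromelysin-1) rose by 2.92 on the log2 scale (SE 0.13). The lipid transporter ABCA12 rose by 2.80 (SE 0.20) and the EGF receptor ligand EPGN (epigen) by 2.78 (SE 0.13). The vesicle-traffic gene RPH3AL rose 9.65-fold, the transcribed pseudogene TPRXL 12.4-fold, MYEOV 5.94-fold, the blood group gene XG 5.70-fold, and PPP2R2C, a regulatory subunit of protein phosphatase PP2A, 5.70-fold. SPANXA1, a cancer-testis antigen on chromosome X, rose 6.26-fold, and it too has near-identical family members. The highest adjusted p of these 10 genes was 3.7e-05, that of PPP2R2C (limma).

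The largest fall measured in both lines was that of NT5M, a mitochondrial nucleotidase, from 3.12 ± 0.12 to -1.17 ± 0.08 (SD, n = 4 each), a 19.5-fold difference (limma, adjusted p = 3.7e-09). ARMCX2 fell 12.8-fold. The mesenchymal transcription factor TWIST2 fell 7.51-fold, the heat shock protein 70 family member HSPA12A 6.33-fold, and BST2 (tetherin), an interferon-induced antiviral membrane protein, 4.19-fold. FKBP10, a collagen-folding isomerase, fell 4.04-fold. The kallikrein KLK1 also fell 4.04-fold. The membrane metalloproteinase ADAM19 and the thioredoxin-related TMX4 fell by 1.94 and 1.87 on the log2 scale. The highest adjusted p of these 9 genes was 2.4e-05 (limma), that of FKBP10. By the rule that picked them, all 4 HSC-3-M3 arrays lay below all 4 HSC-3 arrays in each.

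**Figure D1:**
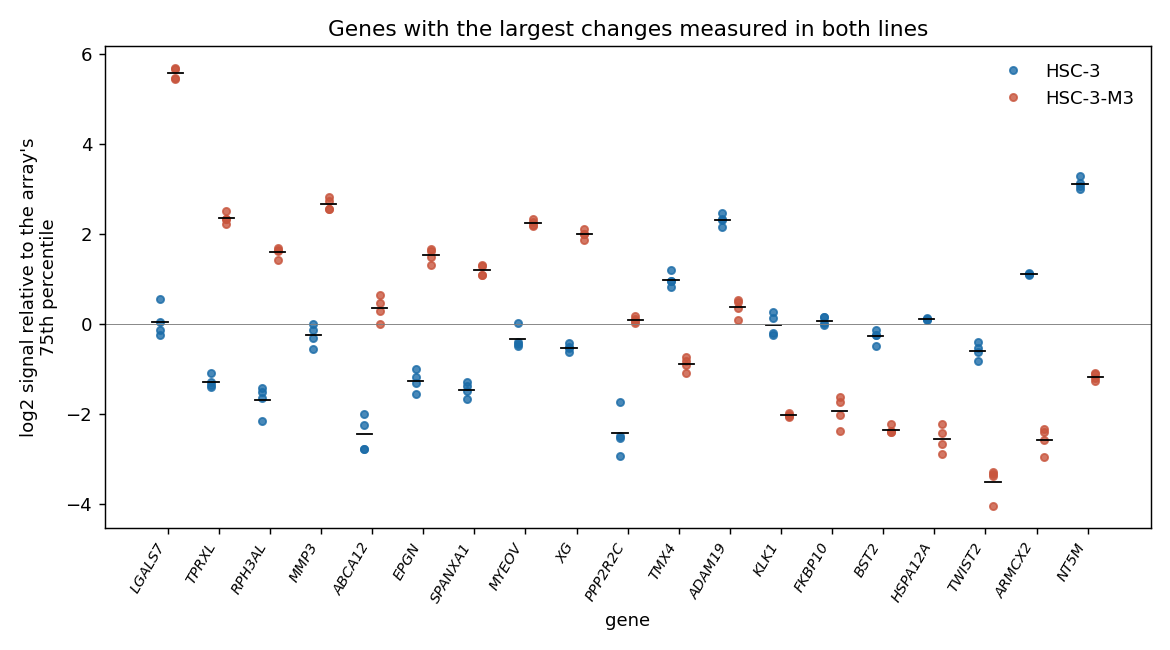
Log2 signal relative to the array's 75th percentile (vertical axis) for the 10 genes with the largest rise and 9 of the 10 with the largest fall that were well above background on all 8 arrays (horizontal axis). Each point is 1 array and each bar the mean of 4. The lines do not overlap in any of these genes, as the rule that picked them required. LGALS7 has means of 0.06 in HSC-3 and 5.56 in HSC-3-M3.

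Some transcripts were measured in 1 line only. NALF1 was well above background on all 4 HSC-3 arrays and on no HSC-3-M3 array. It was at least 22.5-fold lower in the subline, and its fitted fall was 51.7-fold (limma, adjusted p = 1.8e-07). In the same way MAGED1, a MAGE family regulator, was at least 11.04-fold lower. MEST, an imprinted gene expressed from the paternal allele, was at least 8.55-fold lower. The long noncoding RNA TRHDE-AS1 was at least 6.59-fold lower and the arginine methyltransferase PRMT6 at least 5.52-fold lower. In the other direction, the cancer-testis gene SPANXB1 was not well above background in HSC-3 and was at least 4.83-fold higher in HSC-3-M3. IL13RA2, a decoy receptor for interleukin-13, was at least 3.73-fold higher, CYP4F12 at least 3.64-fold, matrix Gla protein (MGP) at least 2.36-fold and the transcription factor SOX6 at least 2.13-fold. The calls of all these rises, from SPANXB1 to SOX6, and that of PRMT6 ended under normexp. Of all genes that passed the test, 52 were measured only in HSC-3 and 13 only in HSC-3-M3.

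In all, 158 genes rose and 175 fell at least 2-fold by the fitted value, with an adjusted p under 0.05 (limma), out of 15106 tested. In 7 of the rises and 21 of the falls 1 line was at background and the lower bound was under 2-fold. Among called genes above background on all 8 arrays, 20 rose and 7 fell 4-fold or more. In 330 of the 333 the arrays of the lines did not overlap. Over all tested genes that share was 26.3%, against the 2.86% that chance gives. Without the fold threshold, 1556 genes rose and 1500 fell. This total of 3056, on whose cut the counts per list below rest, ran from 1536 to 4713 with 1 array left out, and was 923 without scaling and 4973 under median scaling. The called genes include 298 that code for protein and 31 long noncoding RNAs. Scaling each array to its median moved the median change of all genes by 0.20 and gave 251 rises and 130 falls, 65.9% upwards against 47.4%. A normexp background correction of the median spot signal, with an offset, left 63 rises and 37 falls, and 87 genes fell when only probes above background on all 8 arrays were kept.

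The transcription factor NRF2 activates genes for enzymes of glutathione, thioredoxin and NADPH metabolism and for drug efflux pumps. Of 33 such targets tested, 24 rose and none fell at an adjusted p under 0.05; adjusted over the list alone, 26 rose and none fell. The median change was 0.40, and 0.61 under median scaling. SLC7A11, the cystine transporter that feeds glutathione synthesis, rose 3.50-fold (limma, adjusted p = 0.00013), and it is also a target of ATF4. The aldo-keto reductases AKR1C1 and AKR1B10 rose 3.44-fold and 3.12-fold, and the efflux pump ABCC2 3.19-fold; the AKR1C genes are close in sequence. In all, 6 genes of the list rose at least 2-fold. The list mean was 3.81 to 3.87 on the HSC-3 arrays and 4.28 to 4.46 on the HSC-3-M3 arrays. The competitive list test (camera, preset correlation) gave an adjusted p of 1.1e-11, and adjusted p = 0.37 with an estimated correlation.

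Of 44 matrix proteases and inhibitors, 16 rose and 3 fell (adjusted over the list alone, 16 rose and 5 fell). The stromelysins MMP3 and MMP10 rose 7.54-fold and 3.69-fold, and collagenase-3 (MMP13) 4.32-fold. ADAM19 fell 3.85-fold. The MMP3, MMP10 and MMP13 genes are neighbours in the chromosome 11 window from ARHGAP42 to DDX10, whose 35 tested genes had a median change of 0.39 (camera, adjusted p = 6.4e-08, and 0.78 with an estimated correlation). The camera test gave an adjusted p of 0.043 for the list, with a median change of 0.13 (0.34 under median scaling), and adjusted p = 0.53 with an estimated correlation. That call held in 18 of 25 alternatives. It also ended under median scaling (adjusted p = 0.087), under quantile normalization (0.054), with only probes above background on all 8 arrays (0.082), without HSC-3 replicate 1 (0.076), with trends removed (0.063) and on ranks (0.11).

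Of 30 angiogenic and lymphangiogenic factors 10 rose and 2 fell (adjusted over the list alone, 11 and 2). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 2.57-fold. SERPINF1, which encodes the antiangiogenic protein PEDF, rose 2.26-fold, against the name of its list, and its call ended under normexp. The neutrophil chemokine CXCL8 rose 2.18-fold (limma, adjusted p = 0.036), but by 0.80 on the log2 scale without HSC-3 replicate 3, under the fold threshold, and its call ended in 9 of 23 alternatives, 6 of which leave out 1 array. The list had a median change of 0.14 and a camera adjusted p of 0.020, and adjusted p = 0.65 with an estimated correlation. Its median ran from 0.05 to 0.17 with 1 array left out and was 0.34 under median scaling, and its call also ended on ranks (adjusted p = 0.060) and with trends removed (0.063). Among 26 genes of the EGFR family and its ligands, EPGN rose 6.86-fold and epiregulin (EREG) 2.88-fold; 6 rose and 3 fell (12 and 4 adjusted over the list alone), and the list test gave an adjusted p of 0.052. It passed in 9 of 25 alternatives and gave adjusted p = 0.53 with an estimated correlation.

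Of 38 genes of keratinocyte differentiation, 15 fell and 2 rose (adjusted over the list alone, 20 and 3). The median change was -0.30, and -0.09 under median scaling. The kallikrein KLK13 was at least 2.73-fold lower, not being well above background on any HSC-3-M3 array. S100A8, a calprotectin subunit, fell 4.34-fold and suprabasin (SBSN) 3.59-fold. KLK10 fell 3.29-fold. S100A8 was above background on 2 of the 4 HSC-3-M3 arrays and KLK10 on 1 of them. The calls of KLK13, S100A8, SBSN and KLK10 all ended under normexp. The camera test gave an adjusted p of 5.3e-05, and adjusted p = 0.53 with an estimated correlation. The list mean ran from 0.46 to 0.75 over the HSC-3 arrays, lowest in replicate 1 and highest in replicate 3, and from 0.10 to 0.19 over the HSC-3-M3 arrays.

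Basal keratinocyte genes went both ways. Of 26, 5 rose and 6 fell (7 and 6 adjusted over the list alone). SOX2, a stem cell transcription factor, was at least 3.94-fold lower in HSC-3-M3 and not well above background there. Its call ended under normexp. The neurotrophin receptor NGFR fell 2.60-fold and keratin 15 (KRT15) 2.23-fold, a call that ended under median scaling. The collagen receptor integrin alpha-2 (ITGA2) rose 2.19-fold (limma, adjusted p = 0.016), but by 0.85 on the log2 scale without HSC-3 replicate 3, and its call ended in 4 of 23 alternatives. The list's median of 0.02 and its mean of -0.12 differed in sign, the median ran from -0.04 to 0.03 with 1 array left out, and the list test gave an adjusted p of 0.59.

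Of 10 MHC class II genes tested, 7 fell and none rose (8 and none adjusted over the list alone), with a median change of -0.78. HLA-DRA was at least 1.75-fold lower, not being well above background on any HSC-3-M3 array. HLA-DRB5, whose sequence is close to other DRB genes, fell 2.26-fold and was above background on 3 HSC-3-M3 arrays. Both calls ended with trends removed and under normexp, and that of HLA-DRB5 also under median scaling. The camera test gave an adjusted p of 2.0e-04, and adjusted p = 0.53 with an estimated correlation. These are dim transcripts: the list mean ran from -1.67 to -1.17 over the HSC-3 arrays and from -2.22 to -2.11 over the HSC-3-M3 arrays. In contrast, none of 22 genes of MHC class I antigen presentation rose and 2 fell (none adjusted over the list alone), and the list test gave an adjusted p of 0.59. Of 47 interferon-stimulated genes, 4 rose and 10 fell (7 and 12 adjusted over the list alone; list test, adjusted p = 0.15). BST2 fell 4.19-fold, and OASL, above background on 2 of the 4 HSC-3-M3 arrays, fell 2.24-fold with an adjusted p of 0.041 (limma), a call that ended in 13 of 22 alternatives.

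Of 12 leukocyte markers, 5 fell and none rose (6 and none adjusted over the list alone), with a median change of -0.34, and -0.14 under median scaling. The lipopolysaccharide co-receptor CD14 fell 2.23-fold and the lysosomal protein LAPTM5 2.22-fold, and both calls ended under median scaling and under normexp. The camera test gave an adjusted p of 0.0075, and adjusted p = 0.37 with an estimated correlation. Of 6 fibroblast markers 1 rose and 2 fell, of 5 endothelial markers none passed, and of 8 neural and melanocyte markers 1 rose and 2 fell. Adjusted over the list alone these counts were 1 and 2, none, and 2 and 3, and the list tests gave adjusted p of 0.30, 0.36 and 0.36. Of 28 HOX genes, which encode patterning transcription factors, 7 fell and none rose (7 and none adjusted over the list alone), none of them by 2-fold. The HOX median was -0.22, and -0.02 under median scaling. The HOX list had a camera adjusted p of 0.0026, and adjusted p = 0.37 with an estimated correlation and 0.15 with trends removed.

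**Figure D2:**
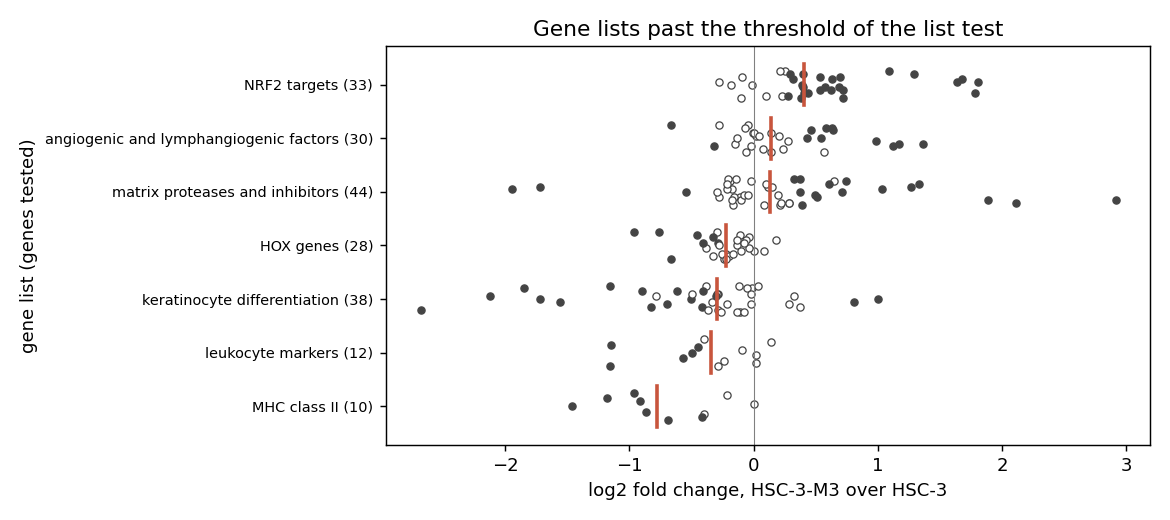
Log2 fold change, HSC-3-M3 over HSC-3 (horizontal axis), of the tested members of the 7 gene lists past the threshold of the list test (vertical axis, with the number of genes). Each circle is 1 gene, filled where its adjusted p was under 0.05, and the red bar is the list's median, which ran from -0.78 for MHC class II to 0.40 for NRF2 targets.

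Single epithelial, mesenchymal and invasion genes had been fixed in advance. E-cadherin (CDH1) was 0.35 higher (SE 0.08, limma, adjusted p = 0.020) and N-cadherin (CDH2) fell by 0.60 (SE 0.09, limma, adjusted p = 0.0022). Under median scaling their changes were 0.55 and -0.39. Neither reached 2-fold, and CDH1 passed in 17 of 23 alternatives and CDH2 in 23. Vimentin (VIM) differed by 0.09 (SE 0.08), SNAI2 by 0.12 (SE 0.12), the splicing regulator ESRP1 by -0.10 (SE 0.08), TP63 by 0.02 (SE 0.09), KRT14 by -0.07 (SE 0.09) and KRT18 by -0.17 (SE 0.10). EGFR differed by 0.07 (SE 0.08), CD44 by 0.19 (SE 0.14), MMP1 by -0.17 (SE 0.08), MMP9 by -0.29 (SE 0.10) and TGFBI by -0.03 (SE 0.08). None of these 11 passed, and the signs of ESRP1, KRT14, KRT18, MMP1 and TGFBI turned under median scaling, those of KRT14 and TGFBI also without scaling, and that of TGFBI also under quantile normalization. The sign of TP63 turned in 8 alternatives, among them 4 that leave out 1 array, and those of EGFR and KRT14 turned when trends were removed. ZEB1 had 2 probes, neither above background on more than 1 array, and was not tested.

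Of 38 genes of epithelial junctions 8 rose and 3 fell (10 and 3 adjusted over the list alone), and of 26 mesenchymal genes 3 rose and 9 fell (4 and 11). Their list tests gave adjusted p of 0.13 and 0.13, and the mesenchymal list passed under median scaling (adjusted p = 0.025). TWIST2 fell 7.51-fold and collagen VI alpha-2 (COL6A2) 2.09-fold, while the calcium-binding protein S100A4 rose 2.09-fold. COL6A2 lost its call in 9 of 23 alternatives. S100A4 changed by 0.93 without HSC-3 replicate 1, and its call also ended under normexp. In the partial EMT program of head and neck carcinoma, 18 of 85 genes rose and 12 fell (22 and 15 adjusted over the list alone; list test, adjusted p = 0.15). Within it MAGED1 was at least 11.04-fold lower. MMP10 rose 3.69-fold and the amino acid transporter SLC7A8 2.19-fold, a call that ended under normexp. The protease inhibitor SERPINE2 rose 2.05-fold, a call that ended in 4 of 23 alternatives, among them 2 that leave out 1 array.

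Of 18 integrins 6 rose and none fell (6 and none adjusted over the list alone), and of 40 laminins, collagens and other matrix proteins 5 rose and 8 fell (5 and 8). The microfibril protein MFAP5 rose 3.94-fold and fibulin-5 (FBLN5), above background on 2 of the 4 HSC-3-M3 arrays, fell 2.71-fold. In the WNT and NOTCH pathway 5 of 46 genes rose and 10 fell (5 and 10). WNT5A, a noncanonical WNT ligand, rose 3.10-fold and HEY1, a NOTCH target, 2.33-fold, while NKD2, an inhibitor of WNT signalling, fell 3.10-fold and the NOTCH ligand DLL3 2.61-fold. Among 41 NF-kappaB targets, cytokines and chemokines, 12 rose and 6 fell (12 and 9). BIRC3, an inhibitor of apoptosis, rose 2.49-fold, CSF2, which encodes GM-CSF, 2.27-fold, and the prostaglandin synthase PTGS2 2.13-fold. Under normexp the calls of FBLN5, HEY1, NKD2, DLL3 and PTGS2 ended. Of 50 genes of cell motility and invasion receptors 8 rose and 4 fell (10 and 5). The cancer-testis list held 13 tested genes, of which SPANXB1, SPANXA1 and SPANXC rose and none fell (3 and 3 adjusted over the list alone). SPANXC rose 5.25-fold. The adjusted p of these 6 list tests was, in this order, 0.28, 0.59, 0.29, 0.48, 0.26 and 0.59. The cancer-testis median of -0.08 and its mean of 0.45 differed in sign; the median ran from -0.26 to -0.02 with 1 array left out and was 0.12 under median scaling.

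Among stress and metabolic lists, 7 of 42 ATF4 and unfolded protein response genes rose and 4 fell (8 and 4 adjusted over the list alone), and 2 of 40 hypoxia and glycolysis genes rose and 7 fell (4 and 7). Of 30 p53 targets 6 rose and 1 fell (6 and 1), and of 35 genes of TGF-beta and BMP response 5 rose and 3 fell (5 and 4). In AP-1 and immediate early genes 3 of 25 rose and 2 fell (3 and 2), and in YAP and TEAD targets 3 of 23 rose and 2 fell (4 and 2). Of 66 cell cycle and proliferation genes 4 rose and 8 fell (1 and 5), of 28 cholesterol synthesis genes 1 rose and 3 fell (1 and 3), and of 46 oxidative phosphorylation genes 1 rose and 1 fell (1 and 1). None of 48 cytosolic ribosomal protein genes passed, nor any adjusted over the list alone, and 2 of 5 simple epithelial keratins fell (1 rose and 3 fell adjusted over the list alone). The adjusted p of these 11 list tests was, in this order, 0.21, 0.36, 0.15, 0.70, 0.58, 0.94, 0.59, 0.77, 0.99, 0.074 and 0.22. The ribosomal protein list passed as lower in 7 of 25 alternatives, and gave adjusted p = 0.83 with an estimated correlation. The list tests used camera, and 7 of 34 lists passed with the preset correlation and none with an estimated one.

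Neighbouring genes on chromosome 10 were lower in HSC-3-M3 over a long stretch. The 7 windows that run from MACROH2A2 to SPRNP1 at the end of the chromosome all passed in the same direction with the preset correlation, and none with an estimated one (adjusted p 0.74 to 0.78). They hold 371 tested genes, with a median change of -0.32 and quartiles of -0.51 and -0.16, and 330 of them lay below the median of all genes. The strongest window, from CPN1 to XPNPEP1, held 72 genes with a median of -0.46 (camera, adjusted p = 3.4e-14, and 0.74 with an estimated correlation). Its called member was the glutathione transferase GSTO2, which fell 3.08-fold. In the window from MACROH2A2 to MBL1P, NUTM2B fell 2.34-fold and UNC5B-AS1 2.28-fold, a call that ended under median scaling and under normexp. The other kept probe of NUTM2B changed by -0.94 on the log2 scale. In the window from PLPP4 to EBF3, C10orf88B was at least 4.20-fold and CUZD1 at least 2.75-fold lower, and the metalloproteinase ADAM12 fell 3.30-fold. The 3 kept probes of ADAM12 changed by -1.72 to -0.86 on the log2 scale. The calls of GSTO2, NUTM2B, C10orf88B and CUZD1 also ended under normexp. Of the 371 genes, 13 were called lower and 1, ABCC2, higher. The other 233 tested genes of the chromosome had a median change of 0.08, but they were not alike. The windows from LOC102723376 to ACTR3BP5 had medians of 0.08 to 0.27. Those next to the stretch, from LOC441666 to COL13A1, had medians of -0.10, -0.15 and -0.13, and none passed. With trends removed these were -0.135, -0.29 and -0.21, and the last passed (camera, adjusted p = 0.013). Where the shift begins is therefore not settled. For the 371 genes of the stretch, the deviation from their mean over the 8 arrays was taken relative to each array's median gene. Its median was 0.14 to 0.20 in the HSC-3 arrays and -0.17 to -0.15 in the HSC-3-M3 arrays.

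Over the genome, 98 of 289 windows passed, 69 higher and 29 lower, and none passed with an estimated correlation, where 7 had an unadjusted p under 0.05. The count was 53 under median scaling, 63 without scaling and 64 with windows of 20 Mb. Over the 275 windows outside chromosome 10, the window median was lower where more genes were tested, with a rank correlation across windows of -0.59; windows are not independent replicates. It also ran along the axis on which replicates of one line differed, on which HSC-3 replicates 1 and 3 lay at opposite ends. With the trend in signal level, gene density and gene length removed, 30 windows passed, 11 higher and 19 lower, 8 of the lower ones on chromosome 10. Elsewhere, that from TPTEP1 to ARVCF on chromosome 22 then had a median of -0.32 (camera, adjusted p = 2.7e-07). That from LINC00548 to CTAGE10P on chromosome 13 had 0.34 (camera, adjusted p = 4.6e-08). That from ARHGAP42 to DDX10 on chromosome 11 had 0.30 (camera, adjusted p = 1.1e-05).

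**Figure D3:**
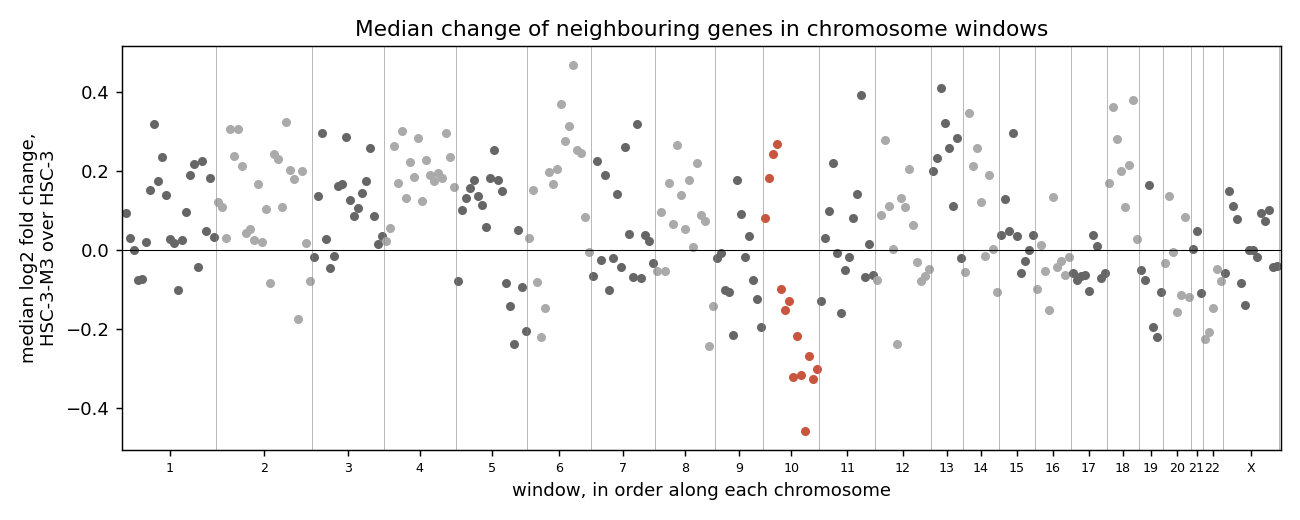
Median log2 fold change, HSC-3-M3 over HSC-3 (vertical axis), of the genes in each of 289 windows with at least 10 tested genes, in order along chromosomes 1 to 22 and X (horizontal axis). Each point is 1 window, chromosome 10 is in red, and its windows from MACROH2A2 on reach a median of -0.46; the other chromosomes alternate in shades of grey.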

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

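Of the tests in this part, those on the share of lowered genes in the chromosome 10 stretch and on random lists matched on signal were chosen only after the results were seen, as was the removal of trends. In 244 groups of 4 arrays (named genes, list means and array measures within a line), 13 had an array whose gap to the next, divided by the range, exceeded Dixon's 95% critical value; chance gives about 12.2. HSC-3 replicate 3 was the array apart for MYEOV (0.853), CDH1 (0.84), SNAI2 (0.847) and the mean of interferon-stimulated genes (0.922). HSC-3 replicate 2 was apart for the mean of the WNT and NOTCH pathway (0.837), and HSC-3 replicate 1 for the mean of AP-1 and immediate early genes (0.896) and for its share of probes above background (0.861), which was 50.7% against 49.0% to 49.3%. In HSC-3-M3, replicate 3 was apart for TWIST2 (0.889) and BST2 (0.882), replicate 1 for NGFR (0.94), WNT5A (0.852) and the mean of fibroblast markers (0.86), and replicate 2 for MMP13 (0.865). Among probes without a gene name here, 14 were well above background on all 4 HSC-3-M3 arrays and on no HSC-3 array, and 59 the other way round.

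A trend and replicate differences were weighed as technical explanations of the lower level of neighbouring genes on chromosome 10. The trend with signal level, gene density and gene length, fitted on the other chromosomes, was removed. The median of the stretch was then -0.37 (95% bootstrap interval -0.40 to -0.34), so that trend does not account for the lower level. The interval resampled genes as if independent, with the arrays held fixed, so it holds no error between samples. The gap between the lowest HSC-3 and the highest HSC-3-M3 array was 0.29, beyond the largest range within a line of 0.06. The stretch was picked for being lower in this same comparison, so a separation of the lines was favoured in advance. No other split was searched for such a stretch, so the gap does not exclude replicate differences. With 88.9% of its genes below the median of all genes (95% exact binomial interval 85.3% to 92.0%, genes not being independent), the shift is not one of a few strongly lowered genes alone. A candidate explanation, as a hypothesis, is a loss of 1 or more copies of this segment in part or all of the subline; no DNA was measured here, copy number measured on DNA of both lines would test it, and position on the slide stays confounded with the line.

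Outside chromosome 10, gene-dense windows were lower and gene-poor windows higher in HSC-3-M3. Over these 275 windows the median change correlated at -0.81 with the genes' weights on the main axis along which replicates of one line differ. The 95% bootstrap interval was -0.85 to -0.78, and such intervals here resampled windows, which are not independent. The axis holds 45.2% of the variance within lines. Signal level does not account for the pattern, since the rank correlation with gene density was -0.61 after its trend was removed (-0.69 to -0.52). Other splits of the 8 arrays gave at least 98 windows in 10 of 35 splits counting the real one, and the highest of the others was 158, so chance cannot be excluded for the number of windows and a structure among the arrays of a line is present. A difference in RNA quality or labelling may lie behind this axis, which was not tested, and no biological explanation was tested.

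The shifts of 3 lists were weighed against signal level, chromosome windows and replicate differences. Against random lists matched on signal, the medians of keratinocyte differentiation and MHC class II lay at percentile 0 and that of NRF2 targets at percentile 100, which argues against a trend with signal. Relative to their window neighbours, NRF2 targets kept a median of 0.44 (95% bootstrap interval 0.32 to 0.58). The intervals here resampled genes as if independent, with the arrays held fixed, so they hold no error between samples. For NRF2 targets the lines were 0.41 apart, beyond the largest range within a line of 0.18. The list was taken up for being higher in this same comparison, so a separation of the lines was favoured in advance. The gap therefore does not exclude replicate differences, and the list did not pass with an estimated correlation (camera, adjusted p = 0.37). A difference in NRF2 activity between the lines stays a hypothesis, open to the confounded slide position. NRF2 protein measured in the nuclei of both lines would test it. For keratinocyte differentiation the corresponding values were -0.20 (-0.32 to -0.03) and a gap of 0.27 against a range of 0.30, and for MHC class II -0.55 (-0.93 to -0.10) and 0.44 against 0.50, so neither windows nor replicate differences could be excluded as part of these shifts. The number of lists called, 7, was matched or exceeded in 2 of 35 splits counting the real one (highest other 8), so chance cannot be excluded for it.

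For the counts of genes, only 1 of the 35 splits, the real one, gave as many as 158 rises, 175 falls or 3056 genes at any fold. The highest of the others was 0 in each. Every other split mixes arrays of both lines, which widens the spread within its groups. These zeros therefore cannot exclude chance, nor the slide position, which is confounded with the line.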

How the results depend on the processing

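The normexp correction on median spot signals, the percentile over detected probes, the unnamed probes, the trend removal and the fit without HSC-3 replicates 1 and 3 were chosen after seeing the data. None of the 72 named genes that were called, and none of the 7 lists that passed, turned its direction under an alternative. Treat and the 1.5-fold threshold were counted but not followed gene by gene. Over the other alternatives 38 of the 72 kept their call, 22 lost it under normexp alone, and 12 lost it elsewhere, CXCL8 in 9 of 23 alternatives, COL6A2 in 9 of 23 and OASL in 13 of 22. Where no cause is named below, the cause was not tested. A limit of signal over background is that dim transcripts have bounds in place of folds.

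Rises numbered 251 under median scaling, 63 under normexp, 536 at 1.5-fold and 50 with treat, and falls 130, 37, 544 and 55. Normexp changed the signal column, the background model and the offset together, so the cause of its drop to 100 calls, all among the 333, is not known. Falls numbered 87 with only probes above background on all 8 arrays, which removes genes lost in HSC-3-M3 by construction. Genes at any fold numbered 4973 under median scaling, 923 without scaling, 1857 without a filter and 6025 with array weights. Leaving out 1 array at a time gave 144 to 178 rises, 161 to 190 falls, 7 to 9 lists and 80 to 120 windows, but 1536 to 4713 genes at any fold. That count moved by over 1.5 times without HSC-3 replicate 1 (4713) or 4 (1676) and without HSC-3-M3 replicate 2 (1748) or 3 (1536). With HSC-3 replicates 1 and 3 both left out, 161 genes rose and 169 fell.

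The replicate numbers did not pair the arrays. Deviations of same-numbered arrays correlated at -0.16, 0.06, -0.30 and 0.09 for numbers 1 to 4, and 1 of the 8 arrays correlated best with its own number. With the number as a block, 157 genes rose, 182 fell and 1668 passed at any fold, and the oxidative phosphorylation list turned relative to other genes with its median still 0.0032.

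Lists passed in number 0 with an estimated correlation (3 at an unadjusted p under 0.05; 11 with the preset one), 19 with directional fry, 32 with mixed fry and 4 with the trend removed. Matrix proteases, angiogenic factors and HOX genes were those lost with the trend. Some lists gained a call: EGFR family and ligands in 9 of 25 alternatives, cytosolic ribosomal proteins in 7, mesenchymal genes under median scaling (adjusted p = 0.025) and simple epithelial keratins under normexp (0.044). Directional fry, which does not compare a list with other genes, passed 12 lists that camera did not. Windows numbered 0 with an estimated correlation, 53 under median scaling, 63 without scaling, 64 at 20 Mb and 30 with the trend removed.

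Reversals concerned genes and lists that did not pass. Under median scaling ESRP1 stood at 0.11, KRT14 at 0.13, KRT18 at 0.038, MMP1 at 0.031 and TGFBI at 0.17, with lists of MHC class I at 0.14, cancer-testis antigens at 0.12 and oxidative phosphorylation at 0.21. Quantile normalization gave TGFBI 0.037, YAP and TEAD targets 0.049 and oxidative phosphorylation 0.047. Without scaling, KRT14 was 0.010, TGFBI 0.051 and oxidative phosphorylation 0.083. Without a filter, oxidative phosphorylation was 0.0032 and endothelial markers 0.031. TP63 was -0.039 with array weights, -0.0094 with the percentile over detected probes, -0.014 without the 2 HSC-3 arrays and -0.048 with the trend removed. YAP and TEAD targets were 0.049 under normexp, -0.0022 with that percentile, -0.0015 without those 2 arrays and 0.025 with fry, where cholesterol synthesis was 0.11. With the trend removed KRT14 was 0.076, EGFR -0.12, MHC class I 0.038, cholesterol synthesis 0.054, YAP and TEAD targets -0.044 and oxidative phosphorylation 0.00067. On ranks the cancer-testis list (-0.084) and oxidative phosphorylation (0.0032) turned relative to other genes. A list's direction is that relative to other genes, so its median can keep its sign. Leaving out 1 array gave TP63 -0.028 to 0.059, oxidative phosphorylation -0.027 to 0.029 and YAP and TEAD targets -0.011 to 0.049. The deposited table of values gave the same 158 rises and 175 falls, being the same signals, so it tests nothing. Normexp on mean spot signals and a slide block were not run.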

Other observations

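Both tests in this part were chosen only after the values were seen. Among 8125 tested features without a gene name here, 40 rose and 55 fell past the same thresholds. Long noncoding RNAs made up 1284 of the tested genes, and 17 of them rose and 14 fell past the fold threshold.

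Transcripts measured in 1 line only were mostly those of the parent. Of the falls, 29.7% (52 genes) were not above background on any HSC-3-M3 array, and of the rises 8.23% (13 genes) on no HSC-3 array. A two-sided Fisher's exact test on these genes gave p = 7.5e-07, but the same counts prompted it, so it decides nothing about a cause. The HSC-3-M3 arrays also had a lower share of probes above background.

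A hypothesis was that zinc finger genes fell more often than they rose. Of 395 genes with a ZNF symbol, 3 were called lower and 1 higher, and the two-sided Fisher's exact test against the other called genes gave p = 0.62. So few called genes could not have given a p under 0.05 in that direction, so this test decides nothing. At any fold 50 rose and 35 fell, so at that cut the hypothesis was not borne out.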
